A study of Mus musculus with 2 samples.

How the data were processed

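Chromatin immunoprecipitation was followed by sequencing in 2 libraries of mouse fibroblasts, 1 with anti-FLAG antibody and 1 with normal mouse IgG. Per the labels' protocols, cells were fixed in 1% formaldehyde for 15 min, chromatin was sheared to an average of 300 to 500 bp, and libraries were made with an Illumina kit for sequencing. The aligner, the genome build and any read filter are not given in the sources used here. The deposited files list tag positions, 1 line per tag, with start, end and strand. The score column of the deposited files holds the constant 512 and was not used. All tags were 36 bp long and no 2 tags of a library shared position and strand, from the deposited files. At this depth some tags would share a position by chance, so duplicates had been removed before deposit. Tag extents fitted the chromosome lengths of build NCBIM37, apart from 3 IgG and 5 anti-FLAG tags beyond a chromosome end, and 0 tags lay wholly in assembly gaps. This build and its annotation, with 37252 genes of which 22350 were protein-coding, were therefore used for coordinates and sequence.

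Groups were taken from the antibody named in the labels. Tests, gene lists, elements and alternatives were fixed before the data were examined, except those named below and in the closing section as added later. Analysis used the 19 autosomes and X, with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. Tags were moved 72 bp downstream, from a lag of 145 bp at which opposite-strand tags of the anti-FLAG library coincided most, 2.28 times chance. In the IgG library the lag was 135 bp and the excess 1.67. The relative strand coefficient that had been planned could not be formed, because 0 opposite-strand tags shared a span. IgG tags were scaled by 0.994, the ratio of library totals, and in an alternative by 0.909, the ratio in 10-kb bins at or below the median count.

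Regions were merged 500-bp windows in steps of 250 bp with at least 10 anti-FLAG tags, at least 2-fold over background and an exact one-sided Poisson p under 1e-05. Background was the largest of the scaled IgG tags in the window, their means over 5 and 10 kb and the genome-wide mean. The same call was made with the libraries swapped. Places were assigned to region centres and to 20000 random tag-covered windows. For the GC correction, the expected tags were multiplied by the anti-FLAG to IgG ratio of windows over 10 kb from every TSS in the same stratum of 2 GC points. Promoters reached 1 kb either side of the 5' end of each protein-coding gene. Those with at least 20 tags in both libraries together were tested with the 2-sided exact conditional binomial test, adjusted by Benjamini-Hochberg at 0.05. Log2 ratios had 1 tag added to each count, and ratios against 0 IgG tags were computed against a floor of 3 counts. Intervals are at the 95% level and cover counting error only.

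The 14 gene lists were compared with 10000 random lists matched on the tags of both libraries in 20 strata, and in an alternative also on GC in 10 strata. With genes of 0 IgG tags placed at the floor and genes at or under it in both libraries left out, the medians of 5 lists moved, the most for G1 regulators, from 1.01 to 1.10. Elements were counted on either strand in 500 bp around region centres and in 10 windows per region matched for GC and for lying within 1 kb of a TSS, with Fisher's exact test. Named genes were Ccnd1, the genes the study is known to have named, the 12 of largest ratio among promoters past the test with an overlapping region and at least 25% of tags on each strand, the 5 of lowest ratio past the test, and per other list the 2 of smallest p. Some genes that this rule names are not reported here. Named regions were the 10 of smallest p, leaving out any with IgG density over 10 times the genome mean.

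The calls were tested on simulated data made by dealing the combined tags at random into 2 libraries. With no difference planted, 157 regions were called in each direction and 0 of 10939 promoters passed. Of 50 regions planted at each level, 4 were recovered at 5 times the genome mean, 46 at 10 times and 50 at 20 times. Of 50 promoters planted at each fold, 7 were recovered at 2-fold, 32 at 3-fold, 39 at 4-fold and 50 at 8-fold, and 5 of 10739 unplanted promoters passed. Promoters that did not pass can therefore hold differences of 2-fold. Alternatives changed the scaling, window size, p threshold, tag shift, promoter width, tag minimum, pseudocount, region test, strand and IgG filter, GC correction, distance to the TSS, profile baseline and element background.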

Results

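The data were 2 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from mouse 3T3 fibroblasts that lack Ccnd1, the gene for cyclin D1, and stably express FLAG-tagged cyclin D1 from a retroviral vector. Cyclin D1 is the G1 cyclin that activates CDK4 and CDK6 and has also been found on chromatin. Sheared, formaldehyde-fixed chromatin was precipitated with the M2 antibody against the FLAG tag in 1 library and with normal mouse IgG, the background control, in the other. The comparison asks where in the genome chromatin was recovered with anti-FLAG beyond what IgG recovered. The anti-FLAG library held 9259840 mapped tags and the IgG library 9312346, of which 9255188 and 9308877 lay on the autosomes and X. With 1 library per antibody there was no replicate check, and each test on tags compares these 2 libraries, not the 2 antibodies in general. All intervals cover counting error only.

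The libraries differed in how they covered GC-rich DNA, far from transcription start sites as well as near them. In 500-bp windows over 10 kb from every annotated transcription start site (TSS), the anti-FLAG to IgG ratio, scaled to library totals, was 0.677 at 24 to 26% GC, 0.955 at 40 to 42%, 1.34 at 50 to 52% and 2.19 at 60 to 62%. The IgG library fell from 2.17 tags per window at 32 to 34% GC to 0.491 at 60 to 62%, while the anti-FLAG library had 1.64 and 1.07 there, with a higher value of 1.89 between them at 42 to 44%. Mouse promoters are often GC-rich. Counts are therefore given as tested against scaled IgG tags and, where it changes them, after correction by the ratio of distant windows of the same GC.

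**Figure D1:**
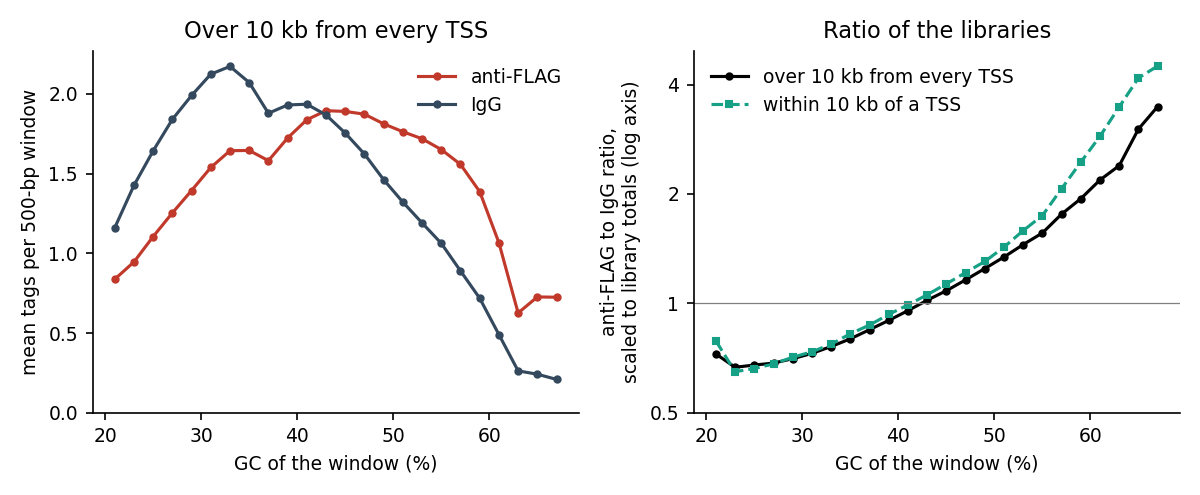
Mean tags per 500-bp window (left) and the scaled anti-FLAG to IgG ratio (right, log axis) against the GC percentage of the window, in strata of 2 points. The ratio rose from 0.677 at 24 to 26% GC to 2.19 at 60 to 62% in windows over 10 kb from every TSS, and at high GC it was higher still within 10 kb of a TSS, 2.88 at 60 to 62%.

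The Ccnd1 locus was examined first, as a check of the genotype given in the labels. Ccnd1 (ENSMUSG00000070348.4) lies on the minus strand of chromosome 7 from 152115836 to 152125774 in build NCBIM37 and has 5 exons. Introns 1 to 3, 4860 bp together, held 0 tags in the anti-FLAG library and 0 in the IgG library, against 17.04 and 17.14 expected at the genome-wide mean. The exact Poisson upper limit was 0.759 tags per kb in each, and the genome-wide means were 3.51 and 3.53. Exons 1 to 3, which flank these introns, were covered in both libraries, with 13.02 anti-FLAG tags per kb (95% exact Poisson interval 6.50 to 23.3) and 7.10 IgG tags per kb (2.61 to 15.5). Intron 4 and exon 5, further towards the 3' end, held 14 and 31 anti-FLAG tags, and 4 and 10 IgG tags. The values thus go with loss of the stretch of introns 1 to 3 in these cells, but not of intron 4. Whether tags can be mapped to introns 1 to 3 was not measured. Over all exons the anti-FLAG library had 11.7 tags per kb (8.56 to 15.7) and the IgG library 4.17 (2.38 to 6.78), while over all introns the values were 2.29 (1.25 to 3.85) and 0.655 (0.179 to 1.68). The window around the Ccnd1 TSS held 8 anti-FLAG and 5 IgG tags, too few for the promoter test. It includes exon 1, which the vector may also carry, and part of intron 1, so its tags do not measure recovery at a promoter.

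**Figure D2:**
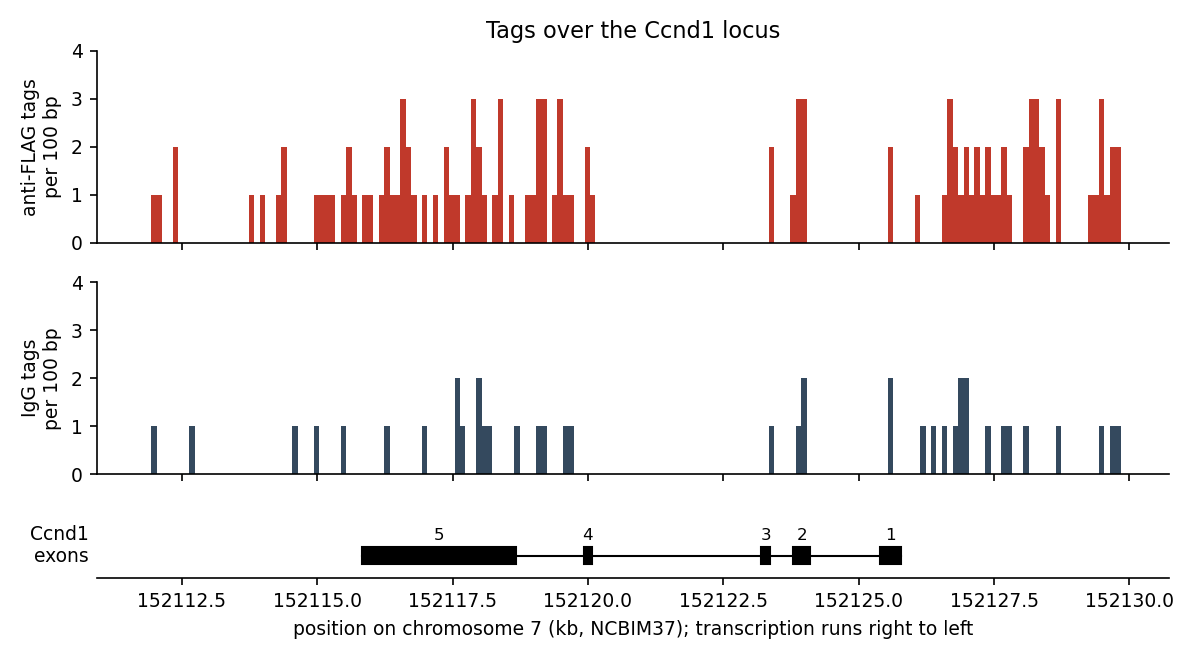
Tags per 100 bp over the Ccnd1 locus and 4 kb either side in the anti-FLAG library (top) and the IgG library (middle), with the 5 annotated exons (bottom) along chromosome 7 in kb. Introns 1 to 3 hold 0 tags in both libraries, while tags lie on exons 1 to 3 beside them.

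Chromatin recovered with anti-FLAG was concentrated at 5964 regions, whereas the same call with the libraries swapped gave 165 regions of IgG excess. The anti-FLAG regions covered 3577500 bp and had a median length of 500 bp, with a median of 16 anti-FLAG and 2 IgG tags in the window of highest significance and a median fold of 5.45 over the local background. They held 1.20% of anti-FLAG tags and 0.187% of IgG tags. A random deal of the combined tags into 2 libraries gave 157 regions in each direction, close to the swapped count. The deal gives both libraries the same GC coverage, and the swapped call favours GC-poor windows. Neither count therefore shows how many anti-FLAG regions come from the difference in GC coverage. With the GC correction there were 3985 anti-FLAG and 92 swapped regions, and 3631 of the 5964 regions, 60.9%, overlapped a corrected one.

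Of the 10 regions named by rank, 5 had as their nearest gene one for a small nuclear RNA (snRNA), most of which are RNA components of the spliceosome, while the 4 of lowest p did not. The region of lowest p was on chromosome 19 from 4988751 to 4989500, with its centre 970 bp from the TSS of Npas4, an activity-regulated transcription factor gene of neurons. It had 71 anti-FLAG against 2 IgG tags in its strongest window, 35.7-fold over the local background (exact one-sided Poisson p = 2.59e-82). This p takes the background as known and leaves out the counting error of the IgG tags. The counts of the other regions below are also those of the strongest window of each. Over their whole length the 10 regions held 53 to 95 anti-FLAG and 3 to 18 IgG tags. A U2 gene (ENSMUSG00000065944.1) had a region on chromosome 11 from 101519501 to 101520500 with 59 against 2 tags, a U5 gene (ENSMUSG00000075930.1) one on chromosome 9 from 65049001 to 65050000 with 55 against 3, and a U1 gene (ENSMUSG00000075736.1) one on chromosome 12 from 55797001 to 55798500 with 55 against 2. A gene for U3, the small nucleolar RNA of ribosomal RNA processing (ENSMUSG00000065870.1), had one on chromosome 10 from 39978001 to 39979250 with 58 against 4. The remaining 3 were an intergenic region on chromosome 15 from 72398751 to 72399500, 22292 bp from the TSS of the potassium channel gene Kcnk9 (67 against 1), an exonic region on chromosome 7 from 6362501 to 6363500 (62 against 3) and an intergenic region on chromosome 12 from 25109501 to 25110500 (53 against 2). All 10 overlapped a region called with the GC correction.

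Regions lay near TSSs more often than tag-covered DNA in general. Their centres were within 1 kb of an annotated TSS in 25.6% of cases (1526 of 5964, 95% exact binomial interval 24.5 to 26.7), against 2.70% of 20000 random tag-covered windows (2.48 to 2.93) and 1.21% of the swapped regions (2 of 165, 0.147 to 4.31). Introns held 32.6% and intergenic DNA 38.5% of regions, against 38.6% and 55.5% of random windows. Exons away from a TSS held 3.27%, against 3.22% of random windows. With the GC correction, added after the data were seen, the share within 1 kb of a TSS was 15.8% (14.7 to 16.98).

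At the TSSs of the 22350 protein-coding genes, anti-FLAG tags stood above and IgG tags below the flanking level. On both sides of this dip IgG tags also stood above that level. Relative to the mean at 4 to 5 kb, anti-FLAG density was highest in the bin centred 75 bp upstream, at 2.25, which is printed as position -75 with the direction of transcription positive. IgG density reached 1.37 at position -525 and was 0.520 at position -25. Within 250 bp of the TSS the densities were 1.88 and 0.697 of the respective baselines, a ratio of 2.69 (95% exact binomial interval 2.66 to 2.73). In 500-bp windows centred on TSSs, anti-FLAG tags were 2.99 times the scaled IgG tags and 1.74 times (bootstrap interval 1.72 to 1.77) the number expected from IgG tags and GC, a comparison added after the data were seen.

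**Figure D3:**
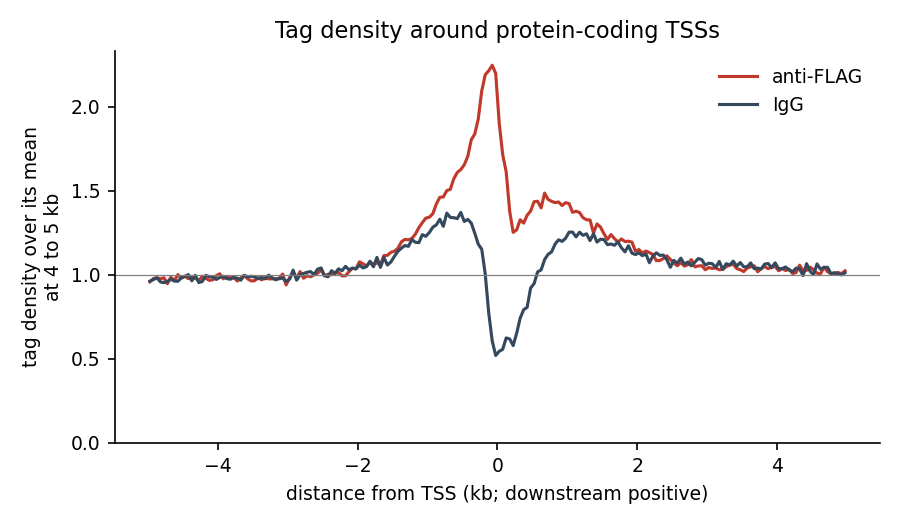
Tag density in 50-bp bins up to 5 kb either side of 22350 protein-coding TSSs, each library divided by its own mean at 4 to 5 kb. The anti-FLAG line peaks at 2.25 just upstream of the TSS, where the IgG line falls to 0.520.

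Per gene, 10945 promoters, 1 kb either side of the TSS, had enough tags to test. Anti-FLAG tags were higher at 3225 of them and lower at 10 (2-sided exact binomial test, Benjamini-Hochberg adjusted p under 0.05). Over all genes the median counts were 11 anti-FLAG and 7 IgG tags. The median log2 ratio over tested promoters was 0.88. The GC correction lowered this median to 0.39 and left 122 higher and 1 lower, and 121 genes were higher in both tests. Scaling to background bins instead of library totals raised the median to 1.00, so the ratios below are to be read against these medians.

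The 12 promoters named for the largest ratios were chosen among those that overlap an anti-FLAG region, and had 0 to 2 IgG tags each. Cyp1b1, Ndufaf3, Ccnd2, Mapk3, Spop, Actb and Large overlapped none of the GC-corrected regions. Cyp1b1, a cytochrome P450 of steroid and xenobiotic metabolism, had 40 anti-FLAG and 0 IgG tags within 1 kb of its TSS at position 80114401 of chromosome 17, at least 13.4-fold higher when 3 IgG tags are taken as the floor (exact 95% lower limit of the ratio 10.4, adjusted exact p = 2.96e-09). Ptbp1, a splicing repressor, had 34 against 1 tags (ratio 34.2, 95% exact interval 5.74 to 1389.9, adjusted exact p = 1.35e-06). Ccnd2, the gene of cyclin D2, and Mapk3, the gene of the kinase ERK1, each had 21 against 1 (ratio 21.1, 3.40 to 873, adjusted exact p = 3.58e-04), as had Rps19, a ribosomal protein gene. Actb, the gene of beta-actin, had 29 against 2 (adjusted exact p = 6.22e-05), and Spop, a ubiquitin ligase adaptor gene, 30 against 2 (adjusted exact p = 4.45e-05). Lphn1, Adamtsl4, Ndufaf3, Tmem191c and Large made up the 12. With the GC correction Ccnd2 and Mapk3 (adjusted exact p = 0.0754) and Rps19 (0.0729) did not pass, and the other 9 did, from adjusted exact p = 1.03e-04 for Cyp1b1 to 0.0481 for Large and Actb. A further TSS lay within 2 kb of the TSSs of Ptbp1, Ccnd2, Lphn1 and Ndufaf3. Among the genes named below by the rule, the same held for Cenpp, Cenpn, Orc1, Chek2, Trp53, Rpl7, Ctgf, Gata6, Actn3 and Olfr1134. The tags of these promoters cannot be assigned to 1 gene. For Rpl27, Brca1, Cbx1 and Olfr449, named below after their values were seen, neighbouring TSSs were not checked.

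The chromosomal instability genes that the study itself is known to have named from this ChIP-seq were considered next. Because the list was chosen on these samples, its result is not independent evidence. Of the 6 genes, 1 passed the test over all genes and 1 when adjusted over the list alone. This was Mlf1ip, also known as Cenpu, a gene of the centromere-associated network, with 59 against 9 tags around its TSS at position 47637409 of chromosome 8 (log2 ratio 2.59, ratio 6.59, 95% exact interval 3.25 to 15.1, adjusted exact p = 4.43e-07). It kept a log2 ratio of 2.38 with the GC correction (adjusted exact p = 4.51e-05). Its ratio depended on promoter width, with a log2 ratio of 3.53 at 500 bp either side (adjusted exact p = 9.44e-08) and 1.03 at 2.5 kb (0.00554). The other 5 had more anti-FLAG than IgG tags without passing in the main test. With 500 bp either side of the TSS, Top2a (log2 ratio 2.81, adjusted exact p = 5.89e-04) and Zw10 (1.52, 0.0193) passed, and Zw10 also passed with background scaling (0.0343) and with tags not shifted (0.0320). With 1 kb either side neither passed with the GC correction (0.719 and 0.477), which was not combined with 500 bp. Zw10, a kinetochore checkpoint gene, had 28 against 13 (log2 ratio 1.06, adjusted exact p = 0.0591), and Cenpp, another centromere gene, 20 against 9 (1.08, adjusted exact p = 0.102). Top2a, the gene of topoisomerase II alpha, had 25 against 14 (0.80, adjusted exact p = 0.157), with a region overlapping its promoter window, as had the GC-corrected call. Ckap2, a spindle gene, had 33 against 24 (0.45, adjusted exact p = 0.348), and Aurkb, the gene of the mitotic kinase Aurora B, 20 against 17 (0.23, adjusted exact p = 0.726). List medians here and below are over all members, with 1 tag added to each count. The median of this list, a log2 ratio of 0.93, stood at percentile 43.9 of 10000 random lists of the same size and tag depth.

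The medians of the other cell cycle lists stood between percentiles 30.9 and 93.4 of random lists of the same tag depth. Counts of higher promoters, here and in the lists below, are to be read against 3225 of 10945 over all tested genes. In mitosis and kinetochore genes 15 of 46 tested promoters were higher, and 15 when adjusted over the list alone (median log2 ratio 0.91, percentile 47.9). The smallest p belonged to Nuf2, a kinetochore gene with 47 against 12 tags (log2 ratio 1.89, adjusted exact p = 2.55e-04, and 0.00953 with the GC correction), and to Cenpn, with 46 against 12. In replication genes and E2F targets the count was 16 of 45, and 19 when adjusted over the list alone (median 1.01, percentile 93.4), with Cdt1, a licensing factor gene, at 52 against 10 (2.28, adjusted exact p = 1.55e-05, and 0.0490 with the GC correction) and Orc1 at 30 against 6. In DNA repair genes it was 10 of 31, and 10 when adjusted over the list alone (median 0.81, percentile 30.9), led by Chek2, a checkpoint kinase gene (38 against 10). In G1 regulators it was 6 of 16, and 8 when adjusted over the list alone (median 1.01, percentile 81.0), led by Ccnd2 and Trp53, the gene of p53 (53 against 16). With the GC correction Nuf2 and Cdt1 were the members of these 4 lists that passed over all genes. Adjusted over the list alone, 5 mitosis and kinetochore genes, 4 replication genes, 2 G1 regulators and 0 DNA repair genes then passed.

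Immediate early and ribosomal protein promoters had the highest list medians with 1 kb either side of the TSS. With 2.5 kb immediate early genes stayed highest (1.30), but fibroblast and matrix genes (0.92) stood above ribosomal protein genes (0.75). Of the immediate early genes, which respond to serum and growth factors, 21 of 23 tested promoters were higher, and 21 when adjusted over the list alone. Their median log2 ratio was 1.75, at percentile 100 of the random lists, and at 99.99 when random lists were also matched on GC. Fos had 28 against 5 tags (log2 ratio 2.28) and Ctgf, a target of serum and Hippo signalling, 31 against 6 (2.20). Of the ribosomal protein genes, 27 of 49 were higher, and 30 when adjusted over the list alone (median 1.30, percentile 99.97). Rpl38 had 28 against 3 (2.86) and Rpl7 33 against 5 (2.51). In Notch, Wnt and Hippo pathway genes 10 of 21 were higher, and 10 when adjusted over the list alone (median 1.18, percentile 99.9), with Fzd7 at 30 against 6 and Wwtr1, the gene of TAZ, at 23 against 5. Matched on GC as well, this list stood at percentile 82.0, and its GC-corrected median of 0.71 at percentile 98.6 of such lists. In fibroblast and matrix genes 13 of 27 were higher, and 17 when adjusted over the list alone (median 1.18, percentile 95.6, and 98.2 when also matched on GC). Acta2, the gene of smooth muscle actin, had 66 against 22 (1.55, adjusted exact p = 1.84e-04, and 0.00911 with the GC correction), and Col1a2 37 against 8. With the GC correction Acta2 and the ribosomal protein gene Rpl27 (36 against 8), named after its values were seen, were the members of these 4 lists that passed over all genes. Adjusted over the list alone, 6 ribosomal protein, 3 fibroblast and matrix, 2 immediate early and 0 Notch, Wnt and Hippo genes then passed. The GC-corrected list medians were lower, 1.07 for immediate early and 0.84 for ribosomal protein genes, at percentiles 99.99 and 99.955 of lists matched on tags and GC.

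The remaining lists had lower medians. In mitochondrial and metabolic genes 9 of 23 were higher, and 9 when adjusted over the list alone (median 0.88, percentile 64.7), among them Pkm2 (30 against 3, which also passed with the GC correction) and Gapdh (30 against 5). The GC-corrected median of this list was 0.29, at percentile 24.3 of lists matched on tags and GC. In nuclear receptors and coregulators it was 4 of 18, and 4 when adjusted over the list alone (median 0.92, percentile 86.2), among them Thra (23 against 6) and, named after their values were seen, Brca1 (24 against 8) and Cbx1 (19 against 6). In Hox and other developmental genes it was 6 of 17, and 6 when adjusted over the list alone (median 0.85, percentile 99.1, and 72.8 when also matched on GC), with Gata6 at 26 against 5. Of genes of other cell types, few of which had enough tags, 1 of 10 was higher, and 1 when adjusted over the list alone (median 0.25, percentile 26.0). This was Actn3, a muscle actinin gene with 34 against 10 tags whose window also holds the TSS of Zdhhc24, while Gcg, the glucagon gene, had 7 against 20 without passing. Olfactory receptor genes, silent in fibroblasts, had a median log2 ratio of -0.22 over 1113 promoters (percentile 0), which was 0.00 with 500 bp either side of the TSS, with 0 higher and 3 lower over all genes (Olfr1446, Olfr1134 and, named after its values were seen, Olfr449) and 0 lower when adjusted over the list alone. Of these promoters 63 had enough tags to test. Matched on GC as well, this list stood at percentile 7.04, and its GC-corrected median of -0.09 at percentile 1.71 of such lists. With the GC correction 0 members of the nuclear receptor, Hox and other cell type lists passed over all genes or when adjusted over the list alone. The medians of these lists were then 0.23, 0.22 and 0.08.

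**Figure D4:**
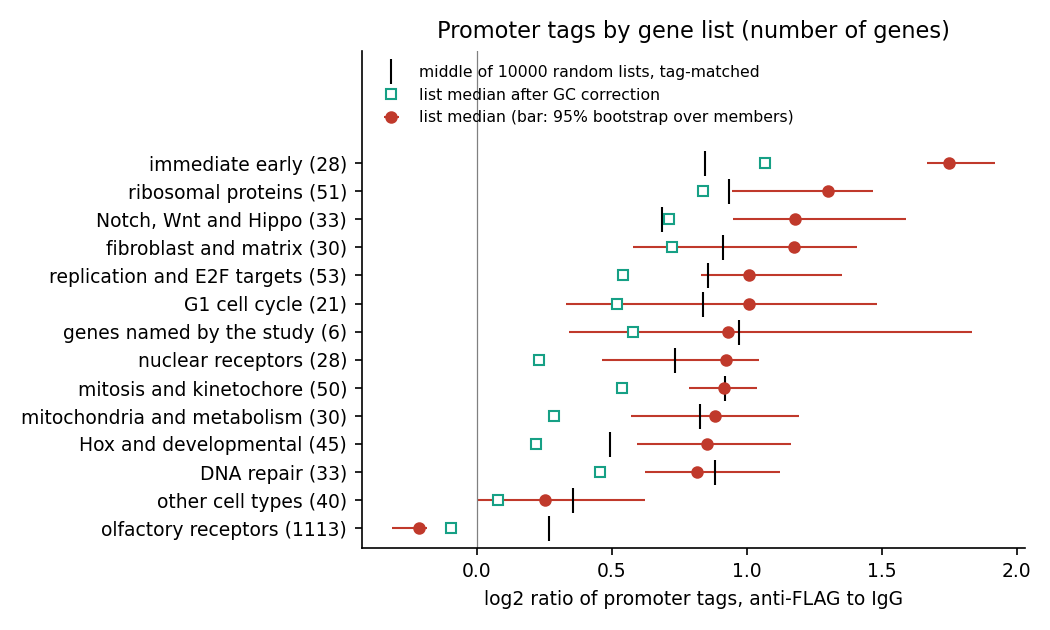
Median log2 ratio of promoter tags, anti-FLAG to IgG, per gene list (circles, with 95% bootstrap intervals over members), the middle of 10000 random lists matched on tags (vertical ticks) and the list median after the GC correction (open squares). Immediate early genes stand highest at 1.75 and olfactory receptors lowest at -0.22, which was 0.00 with 500 bp either side of the TSS.

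Of the 10 lower promoters, the 5 of lowest ratio were those of Tas2r136, a bitter taste receptor gene (2 against 19 tags, ratio 0.106, 95% exact interval 0.0120 to 0.439, adjusted exact p = 0.00351), Hsfy2 (2 against 18), Olfr1446 (3 against 18), Hpgd (4 against 20) and Pign (5 against 22). Hpgd, the prostaglandin dehydrogenase gene, was the 1 gene lower with the GC correction (adjusted exact p = 0.0245). It did not pass with 2.5 kb either side of the TSS (log2 ratio -0.65, adjusted exact p = 0.271), and with 500 bp it held too few tags to test.

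Anti-FLAG regions were enriched for the binding elements of several transcription factors over windows matched for GC and for lying within 1 kb of a TSS or not. Of the 16 consensus sequences fixed beforehand, 13 were more frequent (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05), and 12 among regions called with the GC correction, a comparison added after the data were seen. With the 165 swapped regions as background fewer passed, and E2F, NRF1 and C/EBP sites were not among them. This background was not matched on GC or distance to a TSS, with a median GC of 37% against 48.8% in anti-FLAG regions. It therefore cannot separate enrichment of an element from GC content. The element of CTCF, the insulator protein, was in 5.94% of regions and 0.516% of matched windows (odds ratio 12.2, 95% interval 10.4 to 14.2, adjusted exact p = 1.21e-187). The AP-1 site of Fos and Jun dimers was in 21.1% against 8.06% (3.05, 2.85 to 3.27, adjusted exact p = 3.92e-188), and the site of TEAD, the DNA-binding partner of YAP and TAZ, in 17.3% against 8.001% (2.41, 2.24 to 2.59). ETS sites had an odds ratio of 3.93 (3.38 to 4.56) and E2F sites 1.69 (1.42 to 2.01). C/EBP sites, found in 28 regions and 52 matched windows, had one of 5.45 (3.45 to 8.60), which was 3.34 for regions with p under 1e-07 and 10.7 for GC-corrected regions. NRF1 sites, found in 44 regions and 125 matched windows, had one of 3.56 (2.53 to 5.02), and 6.10 for GC-corrected regions. NF-Y (0.979, 0.913 to 1.05), estrogen receptor and p53 elements did not pass the test, and the estrogen receptor element was found in 4 regions and the p53 element in 0.

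The elements were also counted near and far from TSSs apart, and the difference between the odds ratios was not tested. In regions within 1 kb of a TSS, a split made after the data were seen, the ETS site had an odds ratio of 4.78 (3.98 to 5.72), the CTCF element 4.73 (3.31 to 6.74) and the AP-1 and TEAD sites 1.20 (95% interval 0.985 to 1.46) and 1.18 (0.970 to 1.44). In regions over 1 kb from a TSS the AP-1 site had 3.57 (3.32 to 3.85), the TEAD site 2.82 (2.60 to 3.06) the CTCF element 16.8 (13.99 to 20.1) and the ETS site 2.77 (2.08 to 3.68). The E2F site had 2.08 near TSSs (1.67 to 2.60) and 1.34 far from them (1.01 to 1.78, adjusted exact p = 0.0780). The NF-Y site was more frequent near TSSs (1.68) and less frequent far from them (0.778).

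**Figure D5:**
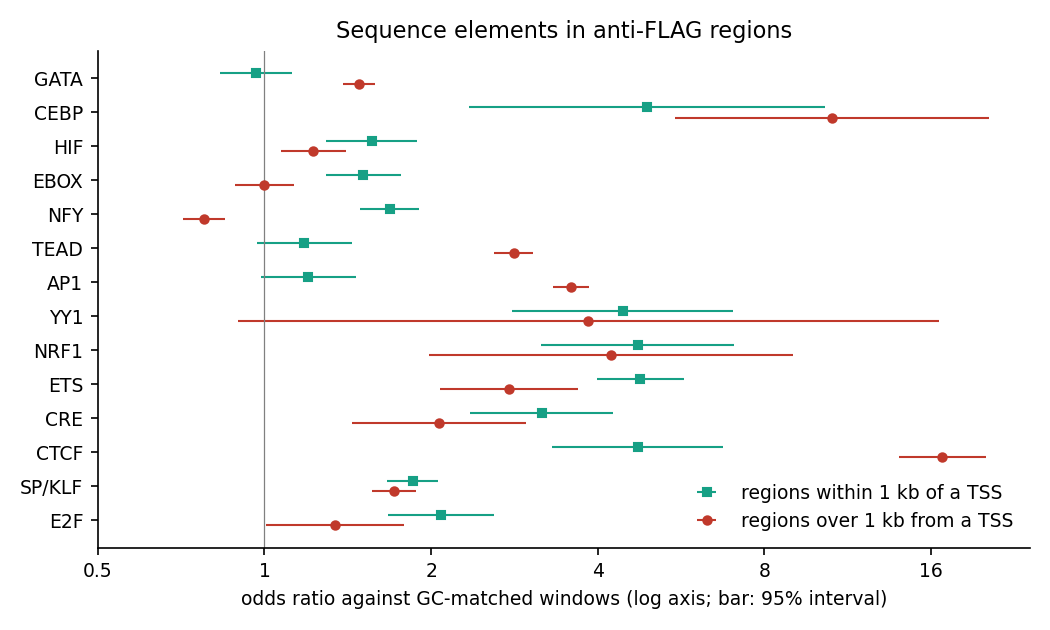
Odds ratio of each element (log axis, bars 95% intervals) in anti-FLAG regions within 1 kb of a TSS (squares) and over 1 kb from one (circles), against windows matched for GC, without the rare estrogen receptor and p53 elements. CTCF reaches 16.8 far from TSSs, and the intervals of AP-1 and TEAD sites exclude 1 there but not near TSSs.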

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

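The tests on GC content for the 3 patterns below were chosen only after the results were seen, and the limit of 50 percent in the test on snRNA genes was restated after its value was known. The CTCF element was taken up as a pattern only after the REST element, weighed first, had shown an odds ratio of 1.12 (95% interval 0.978 to 1.29) over all regions, and 1.36 among GC-corrected regions (exact p = 0.00172). A signal outside the main measurement was present on chromosome M, which the comparisons leave out. It held 4551 anti-FLAG and 3363 IgG tags, a scaled ratio of 1.36 (95% exact binomial interval 1.30 to 1.42). Chromosome Y held 101 and 106 tags, a ratio of 0.958 (0.722 to 1.27).

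Anti-FLAG tags exceeded IgG tags at TSSs. A different loss of GC-rich fragments in the 2 libraries was argued against as the whole cause. In 500-bp windows centred on TSSs the anti-FLAG tags were 1.74 times the number expected from IgG tags and GC (bootstrap interval 1.72 to 1.77), although the uncorrected excess was 2.99. This loss was not excluded, because distant windows over 68% GC were too few to stand alone and were pooled with lower strata. The distant ratio was still rising there, from 2.19 at 60 to 62% GC to 3.48 at 66 to 68%. Recovery that follows promoter activity, with or without cyclin D1, remains a candidate explanation, since ribosomal protein promoters kept a median log2 ratio of 0.84 after correction, at percentile 99.955 of matched lists. The activity of promoters was not measured, and the list of mitochondrial and metabolic genes stood within the spread of such lists (percentile 24.3). Binding of FLAG-cyclin D1 at promoters could give the same values and was not tested, because no anti-FLAG library from cells without the tag was analysed here.

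Genes for snRNAs or U3 lay near 20 of the 200 strongest anti-FLAG regions, though not near the 4 strongest. Of the 35 snRNA genes with a region, 91.4% kept one with the GC correction (exact interval 76.9 to 98.2), which argues against GC content as the cause. The test of tags shared between near-identical copies could not decide. Of the 1412 anti-FLAG tags within 500 bp of these TSSs, 10.9% began inside the annotated snRNA (9.33 to 12.6). The share expected from the length of these genes and the likeness of the copies and their flanks were not measured. The read filter is not known either. What remains open is whether these regions may come from cyclin D1, from tags shared between copies or from recovery by anti-FLAG of very active genes. The part of cyclin D1 and of gene activity was not tested.

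Anti-FLAG regions carried the CTCF element. Windows matched on GC already served for the main odds ratio of 12.2, so the GC percentage of the regions was not the whole cause. Among GC-corrected regions the odds ratio against such windows was 17.8 (14.4 to 21.98), with the element in 232 regions. This test could hardly have come out otherwise, because its windows were matched on GC as well. Chromatin recovered with any antibody may account for part, since at the 12717 consensus sites of the genome IgG tags also stood above the flanks (1.42 times, against 2.21 times for anti-FLAG), a rise 0.352 of the anti-FLAG rise (0.333 to 0.373). The remainder stays open, and a part of cyclin D1 in it was not tested.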

How the results depend on the processing

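The comparisons of regions by place and of elements with the GC correction were chosen only after the results were seen. No paired analysis was possible because each antibody has 1 library. Taking 1 tag per position and strand moved no result, since all positions were distinct, so this setting says nothing on stability. Scaling to background, unshifted tags and the strand and IgG filter left the region counts within 1.5 times (5424 to 7248 regions). At p under 1e-07 there were 2329 regions, 9 swapped regions and 28.0% of regions within 1 kb of a TSS, and 1 element, NF-Y, was less frequent than in matched windows (odds ratio 0.884). A stricter threshold lowers the region counts by construction, and for the share near TSSs and NF-Y the cause was not tested. The binomial test gave 3326 regions and 0 swapped ones. It compared each window with its own IgG tags alone, without the wider background. Its threshold was a Benjamini-Hochberg adjusted p under 0.05 over windows with at least 10 tags in both libraries together. Its counts therefore differ from the main call in more than the test. With 300-bp windows there were 87 swapped regions, and the cause was not tested. Counted to 5 kb from a TSS by construction, 38.4% of regions were near. With the genome-wide mean as baseline the TSS ratio was 2.99. Promoters of 500 bp either side gave 1885 higher and 3 lower, with 3006 tested, and 18 of the 48 named genes passed. In the same setting the olfactory median reversed to 0.00 (0.00417), and the cause was not tested. Of the 14 list medians, 7 moved at 500 bp, 7 at 2.5 kb, 10 with the GC correction, 6 with a pseudocount of 5 and 1 with background scaling, and that of ribosomal protein genes went from 1.30 to 2.01 at 500 bp and 0.75 at 2.5 kb. Promoters of 2.5 kb gave 2132 higher and 30 lower, with 20308 tested. Without a tag minimum 2663 were higher and 16 lower, with 21702 tested, and at a threshold of 0.01 there were 1355 higher and 2 lower. The GC correction gave 122 higher and 1 lower promoters, 15 of 48 named genes past the test instead of 41, 92 swapped regions, 15.8% of regions within 1 kb of a TSS and 1 element less frequent than in matched windows, NF-Y (0.823). By its construction it raises the tags expected in GC-rich windows. With swapped regions as background, which are 165 in number, 5 elements were more frequent (SP/KLF, CTCF, ETS, AP-1 and TEAD). GATA was less frequent, its odds ratio reversed to 0.555. This background was not matched on GC or distance to a TSS and was poorer in GC (median 37% against 48.8%). These changes therefore cannot be told apart from a difference in GC content. Among single named genes the GC correction left 26 no longer past the test, 500-bp promoters 25, most of them because they then held too few tags to test, and 2.5-kb promoters 11. Calls were gained for Top2a and Zw10 at 500 bp, for Ccnd1 at 2.5 kb (adjusted exact p = 0.0497), for Zw10 with background scaling and for Zw10 and Gcg with unshifted tags. None of the genes past the test changed direction, and Ccnd1, which was not tested, went from a log2 ratio of 0.59 to -0.10 with the GC correction. The Ccnd1 windows hold intron sequence without tags and exons that the FLAG-cyclin D1 vector may also carry. Their values therefore do not measure recovery at a promoter. Depth limits how many promoters could be tested, 10945 of 22350, although fewer were higher without the tag minimum (2663) than with it (3225).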

Other observations

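All tests in this part, on gene classes, on the strongest regions and on sites across the genome, were chosen only after the results were seen. The class tests count each gene as independent, although neighbouring genes can share a region, so their p-values may overstate the evidence. Histone genes, which encode the core of the nucleosome, often held a region. Within 500 bp of the TSS, 20 of 63 had one (31.7%), against 4.90% of all other genes with tags (odds ratio 9.02, adjusted exact p = 3.95e-11 over 16 classes), and 11 had one with the GC correction (odds ratio 10.9, adjusted exact p = 1.25e-07). Of genes for U5, a spliceosomal RNA, 7 of 10 had a region (odds ratio 45.0, adjusted exact p = 1.74e-07, and 119.96 with the GC correction), and of those for U3 5 of 29 (4.01, adjusted exact p = 0.0174, and 10.7 with the GC correction). Over all 1386 snRNA genes with tags, 35 had one (2.53%, odds ratio 0.487, adjusted exact p = 8.62e-06). After the GC correction 33 had one, and the odds ratio was 1.25 (adjusted exact p = 0.263). Of 914 U6 genes 8 had a region, and 7 with the GC correction. Pseudogenes had a region in 16 of 4512 cases. Of the 200 regions of smallest p, 20 lay near an snRNA or U3 TSS, against 18 of the other 5764 (odds ratio 35.5, exact p = 2.48e-20).

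The element of REST, a repressor of neuronal genes, with up to 2 mismatches, was in 24 of these 200 regions, 12% against 3.80% of matched windows (odds ratio 3.49, exact p = 4.38e-06). Over all 5964 regions it was in 3.82% against 3.42% (odds ratio 1.12, exact p = 0.110), with an odds ratio of 1.36 (exact p = 0.00172) in GC-corrected regions and 1.35 (exact p = 0.00477) in 200 bp around the centre, and in the next 800 regions the odds ratio was 1.05. The B box of genes read by RNA polymerase III was in 1.11% of regions against 0.223% of windows (5.03, 95% interval 3.74 to 6.75). At all 7232 sites of the genome within 1 mismatch of the REST element, anti-FLAG tags were 1.38 times the flanks (bootstrap interval 1.33 to 1.43) and IgG tags 0.992 times (0.972 to 1.02). At 418686 AP-1 sites the values were 1.16 and 1.09, and at 635561 RUNX sites 1.02 and 1.01.

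Tag density differed between chromosomes in both libraries. Relative to the median chromosome, chromosome 19 had 1.55 in the IgG and 1.61 in the anti-FLAG library, chromosome 8 had 1.35 in each, and X had 0.669 and 0.580. The anti-FLAG to IgG ratio of X was 0.876 (95% interval 0.872 to 0.880), and 0.972 (0.967 to 0.976) of that expected from its GC content.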
